A study of Mus musculus with 16 samples.

How the data were processed

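Tail DNA of 8 mice of 1 family (sire, dam, 6 progeny) was compared with tail DNA of 1 reference male on 16 two-colour oligonucleotide arrays, with 2 arrays per animal that exchange the dyes. Labels gave the family role and the dye of each sample. The design text also mentions a secondary array screen and quantitative PCR assays, which were not used here. Scans fell on 4 days, with progeny 1 and 2 on the first, the parents on the second, progeny 3 and 4 on the third, and progeny 5 and 6 on the fourth.

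Per the file headers, the authors extracted the arrays with Agilent Feature Extraction 10.7.1.1, and the deposited array files give a log10 ratio of red (Cy5) over green (Cy3) after background subtraction, detrending and linear dye normalization. The deposited array files also give each channel's intensity, processed and as the median of the spot's pixels with its local background. The deposited value table holds log2 ratios of reference over animal on every array, already turned for the dye; how it was made is not stated, and its medians lay between -0.0065 and 0.0177. It correlated with the scanner ratio at 0.993 to 1.00 in size. The table served as an alternative, and the scanner ratio as the source of all values reported.

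The log10 ratios were converted to log2 and turned to animal over reference. Spots marked as outliers by the scanner (124 to 395 per array) and controls were left out, the spots of a probe were averaged, and each array was centred on its autosomal median. No spot was saturated (0 on each array). Between 96.1% and 99.8% of spots were well above background in each channel. Median background-subtracted signals were 46.3 to 126 in green and 57.3 to 141 in red, and the number of arrays limits the precision. There were 36 probes on unplaced contigs, which were left out. X and Y were summarised as medians and left out of the searches. Direction was settled by the Y ratios.

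Autosomal calls used an interval score: the sum of the mean of both orientations over an interval, divided by the spread between neighbouring probes and the square root of the number of probes. Intervals of up to 1000 probes were searched, best first. A call needed a score of at least 6, at least 3 probes, an absolute mean of at least 0.25 and at least 0.125 in each orientation. The same search was run on the 2 orientations subtracted, which keeps the dye effect and removes the animal's signal, as an estimate of the background. Each search was scaled to its own spread between neighbouring probes, 0.18 to 0.24 for this difference and 0.133 to 0.192 for the mean. At the same score the difference had to reach a larger ratio, so its counts may understate the background. The search was tested on simulated data with 20 changes planted per size: changes of 10 or more probes at 0.58 were recovered at 100% in the noise of each of 3 animals, and changes of 3 probes at 0.58 at 10% to 45%. False calls numbered 28 and 22 in the noise of the sire and progeny 3, and 1030 in that of progeny 1. Of these, 0, 0 and 14 had at least 5 probes and a score of 8. This search started from 3 probes, unlike the stricter search below, which started from 5. The simulation shuffled the ratios of each array separately within a chromosome. It thus broke the link between the 2 arrays at a probe and between neighbours, so these counts are no false-call rates of the real search.

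Calls of the same direction that shared a probe were merged, with the probes found in at least 50% of a region's calls. An animal carried a region if its mean reached 0.25 and each orientation 0.125. Regions were classed by carriers as all animals, parent and progeny, parent alone, or progeny and neither parent. A candidate was a region of the last class in which a progeny differed from each parent by at least 0.25 in both orientations. A planned comparison of this difference with random windows of the genome was left out of the results, because regions picked by the search for a large difference exceed unselected windows by construction. The naming rule took the 10 candidates with the largest difference and, of each other class, the 5 regions with the largest mean among those with at least 5 probes. The outcomes, tests, naming rule and most alternatives were set before the data were examined.

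The probe test was limma 3.58.1 in R 4.3.3 on the mean of both arrays per animal, with groups progeny and parents. It tested the progeny mean against 0 and the progeny against the 2 parents, with Benjamini-Hochberg adjustment, and called an adjusted p under 0.05 with an absolute log2 value of at least 0.25. In simulated data with 50000 independent probes, 100 were changed by 0.5 and 100 by 1 in every progeny. The test recovered 85% and 99% of these against the reference. The real test held 949333 probes, and the adjustment is harsher where changes are sparser, so these shares may be too high. In the chromosome 13 gain described below, at a median of 0.505, 10 of 26 probes were called. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

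Alternatives were the value table, normexp background correction with an offset of 50 (on median signals, since the array files hold no mean signals), other scores, probe minimums and ratio minimums, each orientation alone, leaving out probes whose reference spot was not well above background on all arrays (877412 autosomal probes remain), limma variants, and leaving out each animal. Chosen after the data were seen were a scan day block, calls without progeny 1, the mean without the most extreme probe, and leaving out uneven areas. For the last, each array was divided into 1600 tiles, and tiles whose SD exceeded 1.5 times the array's median tile SD were dropped, alone or together with a minimum of 5 probes and a score of 8. This removed 59 tiles (3.72% of spots) from the progeny 1 array with the animal in Cy3, 9 tiles (0.559%) from that of progeny 6 and at most 6 from any other array.

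The planned gene-level tests and the 15 gene lists were not run, because the gene annotation at hand is on a later build than mm9 and holds no mm9 positions. Correction for GC content was not run, since no genome sequence was at hand. These files held no other family, so no comparison between families of different treatment was possible.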

Results

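Comparative genomic hybridisation compared tail DNA of 1 mouse family of strain C57BL/6JNrs with tail DNA of 1 reference male from the colony. The family held a sire, a dam and 6 progeny. Each of these 8 animals was hybridised on 2 arrays, once labelled with Cy3 and once with Cy5 (a dye swap), which made 16 arrays and 1 replicate per animal. The series title names a male exposed to gamma rays at 1 mGy per day for 400 days, while the design text calls the sire of this family non-irradiated, so the treatment of this sire was not settled by the labels. No other family was at hand, and an effect of radiation was not analysed here. Each array held 966371 non-control spots for 950749 probes, of which 950622 lay on autosomes (mouse build mm9) with a median spacing of 2053 bp, and 68 on X and 23 on Y. Log2 ratios are animal over reference throughout, as the mean of both arrays of an animal. The errors given are standard errors (SE) over the probes of a region within an animal; they hold no spread between animals. Values of regions of 10 or more probes leave out the unevenly scattered areas of each array, except those under another background correction (normexp), which keep them. Genes at these positions were not named, since the files gave mm9 positions alone.

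The first comparison asked how far the 2 dye orientations of each animal carried the same signal. The 2 arrays of an animal, turned to animal over reference, correlated negatively across probes in all 8 animals (Pearson's r from -0.490 in progeny 2 to -0.122 in progeny 6; probes are not independent replicates). Arrays of different animals with the same dye correlated positively in all 56 pairs, with a median r of 0.213. The spread between neighbouring probes was 0.217 to 0.304 on single arrays. It fell between 0.133 and 0.192 for the mean of both arrays, highest in progeny 3 and progeny 4, whose arrays were also the dimmest in both channels except for the red channel of 1 progeny 6 array.

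On the sex chromosomes the animals fell into 2 sets. The median ratio over the 68 X probes was 0.90 in the dam (SD over probes 0.185), 0.97 in progeny 5 (SD 0.192) and 0.93 in progeny 6 (SD 0.226). It was 0.01 in the sire and between -0.02 and 0.00 in progeny 1 to 4. Over the 23 Y probes the median was -2.13 in the dam (SD 1.09), -2.86 in progeny 5 (SD 1.09) and -2.23 in progeny 6 (SD 1.13), against 0.03 in the sire and -0.04 to 0.08 in progeny 1 to 4. The reference is a male, and the labels give no sex for the progeny. Under another background correction (normexp) the X values of the dam, progeny 5 and progeny 6 were 0.62, 0.63 and 0.49, and the Y values -0.28, -0.20 and -0.35. Normexp added an offset of 50 to both channels, which pulls ratios toward 0 by construction. The thresholds for calls and carriers below stayed the same under normexp.

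The next comparison searched each animal for autosomal stretches that differed from the reference. A gain of 74 probes on chromosome 4, a gain of 26 probes on chromosome 13 and a loss of 97 probes on chromosome 14 were each carried by at least 6 of the 8 animals, and are described with the merged regions. Calls of 10 or more probes numbered 15 in progeny 1 and 2 to 9 in each other animal. In all, the search made 2944 calls, of which 83.0% spanned 3 probes. Progeny 1 had 1519 calls, 1477 of them losses. The sire had 270 calls, the dam 195, progeny 2 had 118, progeny 3 had 248, progeny 4 had 245, progeny 5 had 148 and progeny 6 had 201. The same search on the difference between the 2 orientations, in which a real difference in copy number cancels, gave 785 calls in progeny 1 and 14 to 119 in each other animal. The orientation difference had a wider spread than the mean in every animal, so the same score needed a larger ratio and these counts may run low. Of all calls, 1127 (38.3%) kept a mean of at least 0.25 without their most extreme probe, and so did 673 of the 1301 calls on the orientation difference. Without progeny 1 the count was 1425. With the unevenly scattered areas of each array left out, a step chosen after the data were seen, the count was 1645, with 248 in progeny 1 and 539 on the orientation difference.

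**Figure D1:**
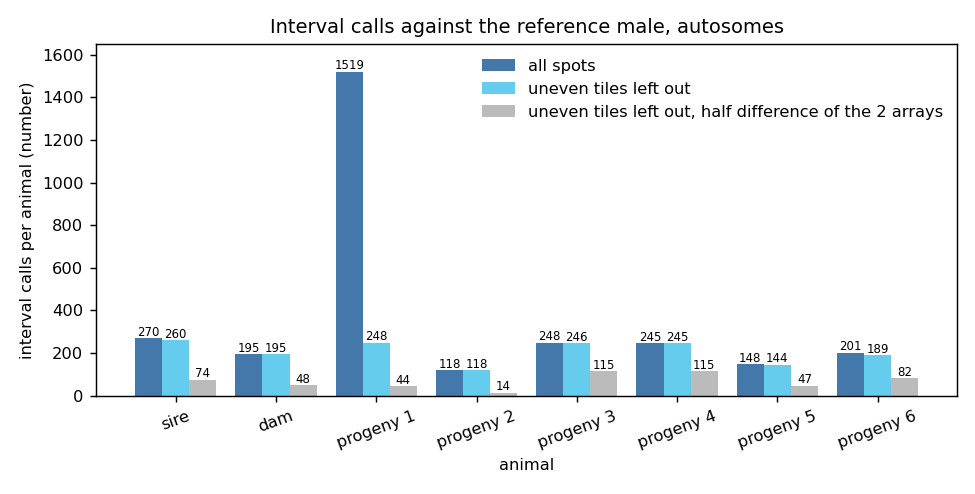
Interval calls per animal on the autosomes, with all spots, with uneven areas of the arrays left out, and for the orientation difference with the same areas left out. Bars are counts; progeny 1 falls from 1519 to 248 calls once the uneven areas are left out, and the dam stays at 195.

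**Figure D2:**
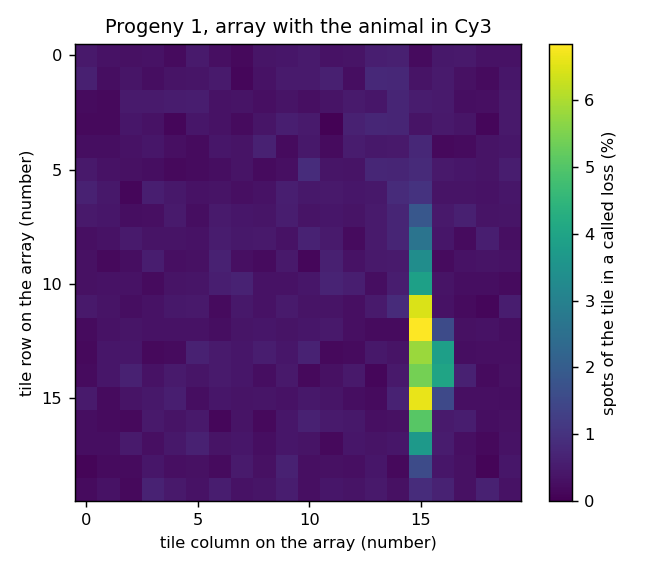
Percent of the spots in each of 400 tiles of the progeny 1 array with the animal in Cy3 that lie in a called loss, by tile row and column. The densest 20 tiles hold 32.2% of these spots.

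Overlapping calls were merged over the 8 animals to ask which changes parents and progeny shared. A gain on chromosome 13 from 65468928 to 66973977 (1505 kb, 26 probes) was carried by all 8 animals, at 0.49 ± 0.056 in the sire, 0.43 ± 0.054 in the dam and 0.46 to 0.58 in the 6 progeny. Under normexp it was lower, with 0.29 in progeny 3 as the lowest value and 0.43 in progeny 2 as the highest. A gain on chromosome 4 from 101110482 to 101270535 (160 kb, 74 probes) was carried by 7 of the 8 animals. It stood at 0.56 ± 0.018 in the sire, 0.94 ± 0.017 in the dam and 0.53 to 0.60 in progeny 2 to 6, while progeny 1 gave -0.01 ± 0.024. Under normexp the 7 carriers ranged from 0.37 in progeny 4 to 0.80 in the dam, and progeny 3 gave 0.38. A loss on chromosome 14 from 53414208 to 54345421 (931 kb, 97 probes) was shallower, at -0.28 in the sire, -0.26 in the dam and -0.33 to -0.18 in the progeny. Progeny 5 (-0.18) and progeny 6 (-0.25) lay under the carrier threshold of 0.25 there, and the dam did so (-0.248) without its most extreme probe. Under normexp all 8 animals lay under it, from -0.23 in progeny 2 to -0.15 in progeny 6. All ratios share 1 reference mouse, and a change in that mouse in the other direction would appear in all 8 animals. The gain on chromosome 13 and the loss on chromosome 14, negative in all 8 animals, cannot be told apart from such a change.

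Some changes were carried by the dam and progeny 5 and 6 alone, the 3 animals that also had the high X and low Y ratios. A gain on chromosome 8 from 102132083 to 102245478 (113 kb, 40 probes) stood at 0.28 ± 0.028 in the dam, 0.28 ± 0.040 in progeny 5 and 0.25 ± 0.029 in progeny 6, and between -0.01 and 0.02 in the other 5 animals. Without the most extreme probe progeny 6 gave 0.24. Under normexp the gain was 0.26 in the dam, and progeny 5 (0.23) and progeny 6 (0.24) lay under the threshold. A loss on chromosome 3 from 25417435 to 25432738, of 3 probes, stood at -1.52 ± 0.27 in the dam, -1.53 ± 0.30 in progeny 5 and -1.68 ± 0.27 in progeny 6, with the sire at 0.03. Over 6 probes of the locus (25414118 to 25446265) in the stricter search it was shallower, at -0.84 ± 0.340, -0.83 ± 0.344 and -0.73 ± 0.319. These regions and the chromosome 14 loss were chosen after their values were seen, while the gains on chromosomes 13 and 4 were named by the rule fixed beforehand.

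By class, 2836 merged regions were found, 723 gains and 2113 losses. All 8 animals carried 2 of them, the other being a gain of 3 probes on chromosome 13 from 95707465 to 95712034. A parent and progeny shared 230 regions, a parent alone carried 299, progeny and neither parent carried 2301, and 4 had no carrier over their common probes. The same steps on the orientation difference gave 1268 regions, of which 937 fell to progeny and neither parent, 301 to a parent and progeny and 29 to a parent alone. Of those shared by a parent and progeny, that rule further named a gain on chromosome 2 from 21348406 (sire 0.28, progeny 3 0.70) and a loss on chromosome 9 from 76885040 (sire -0.54, progeny 4 -0.26). It also named a gain on chromosome 1 from 157068940 (dam 0.43, progeny 2 0.34) and a loss on chromosome 3 from 106487596 (sire -0.32, progeny 6 -0.43). Each of these 4 had 5 probes, and in each a carrier fell under 0.25 in size without its most extreme probe. The sire then gave 0.04 on chromosome 2, -0.21 on chromosome 9 and -0.21 on chromosome 3, progeny 4 gave -0.13 on chromosome 9, and on chromosome 1 the dam gave 0.09 and progeny 2 gave 0.22. Of the regions of a parent alone, it named losses in the sire on chromosome 12 from 109261341 (-0.47) and chromosome 2 from 89256924 (-0.44), and gains in the sire on chromosome 3 from 13734851 (0.42) and chromosome 2 from 77349535 (0.40). The remaining one was a gain in the dam on chromosome 3 from 154663695 (0.40, 6 probes). Without the most extreme probe the dam's gain (0.33) and the sire's loss on chromosome 2 (-0.295) kept 0.25 in size, and the other 3 did not. Without progeny 1, 1342 regions were found, 836 of them in progeny and neither parent. Normexp left 298 regions in all, 19 of them shared by a parent and progeny and 5 in a parent alone, and the strictest search left 9 and 5. A minimum mean of 0.4 left 57 shared regions.

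**Figure D3:**
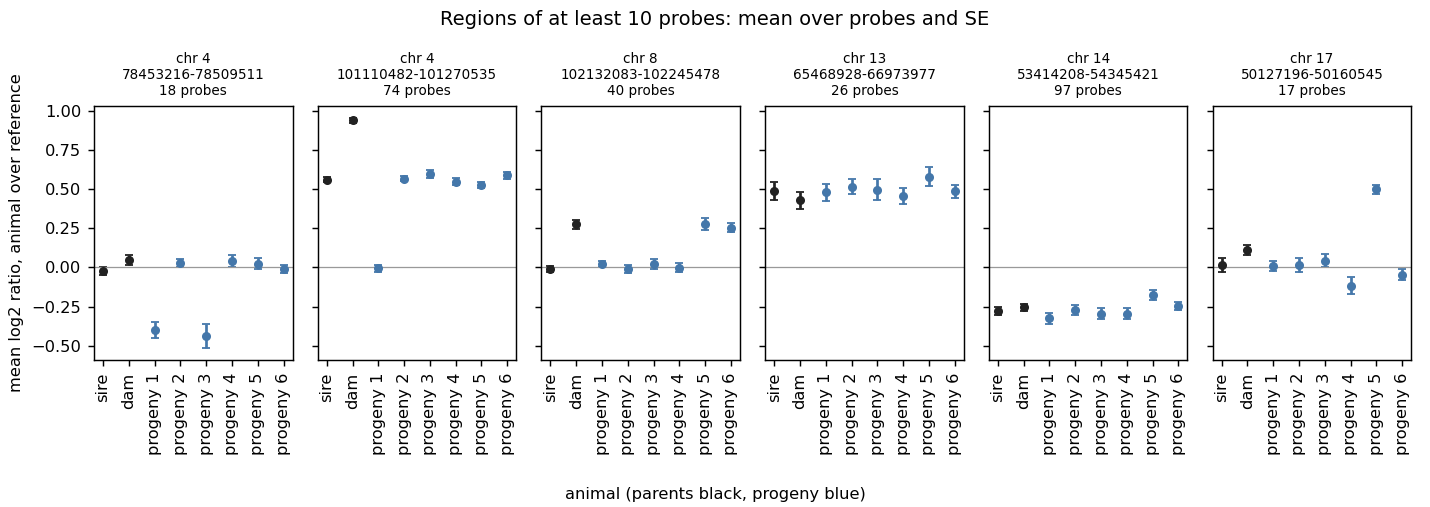
Mean log2 ratio, animal over reference, in each of the 8 animals (parents black, progeny blue) for the 6 regions of at least 10 probes that passed the stricter search; bars are SE over probes. On chromosome 4 from 101110482, 7 animals sit between 0.53 and 0.94 and progeny 1 at -0.01.

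The family design also asks which regions appeared in progeny and in neither parent. The strongest was a gain on chromosome 2 from 70079530 to 70085630 (4 probes), present in progeny 1 (4.39), progeny 2 (4.33), progeny 3 (3.41) and progeny 4 (3.27). It was absent from the sire (-0.29), the dam (-0.21), progeny 5 (0.21) and progeny 6 (-0.05). In each of progeny 1 to 4, 8 of 8 animal spots lay well above background, against 0 of 8 in each of the other 4 animals, and 0 reference spots did so on any array. Progeny 1 to 4 are also the progeny with X and Y ratios near 0, and the sire, with like ratios, lacked the signal. They also fill 2 of the 4 scan days, while the 4 animals without the signal fill the other days. Since the reference gave no signal, the ratios are no fold changes. Against the dimmest reference spot called well above background they are at least 5.20-fold, 6.12-fold, 2.88-fold and 2.65-fold for progeny 1 to 4. Among all spots of its channel, the signal of progeny 1 to 4 lay at percentiles 22.4 to 31.2. In the other 4 animals it lay at percentiles 0.02 to 0.107. Gain here thus means signal that the reference and these 4 animals lacked, and the values do not show extra copies.

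A loss on chromosome 4 from 78453216 to 78509511 (56.3 kb, 18 probes) stood at -0.40 ± 0.051 in progeny 1 and -0.44 ± 0.078 in progeny 3, with the sire at -0.02, the dam at 0.05 and the other 4 progeny between -0.01 and 0.04. The difference from the nearer parent was 0.376 in progeny 1 and 0.416 in progeny 3. On single arrays the loss was -0.24 with progeny 1 in Cy3 and -0.54 in Cy5, and -0.38 and -0.50 for progeny 3. A gain on chromosome 17 from 50127196 to 50160545 (33.4 kb, 17 probes) stood at 0.50 ± 0.029 in progeny 5, against 0.02 in the sire, 0.11 in the dam and -0.12 to 0.04 in the other 5 progeny. Its difference from the nearer parent was 0.387. Under normexp the chromosome 4 loss weakened to -0.28 in progeny 1 and to -0.24, under the threshold, in progeny 3, and the chromosome 17 gain to 0.39 in progeny 5. These regions were chosen after their values were seen, from a stricter search (5 or more probes, score 8, uneven areas left out).

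**Figure D4:**
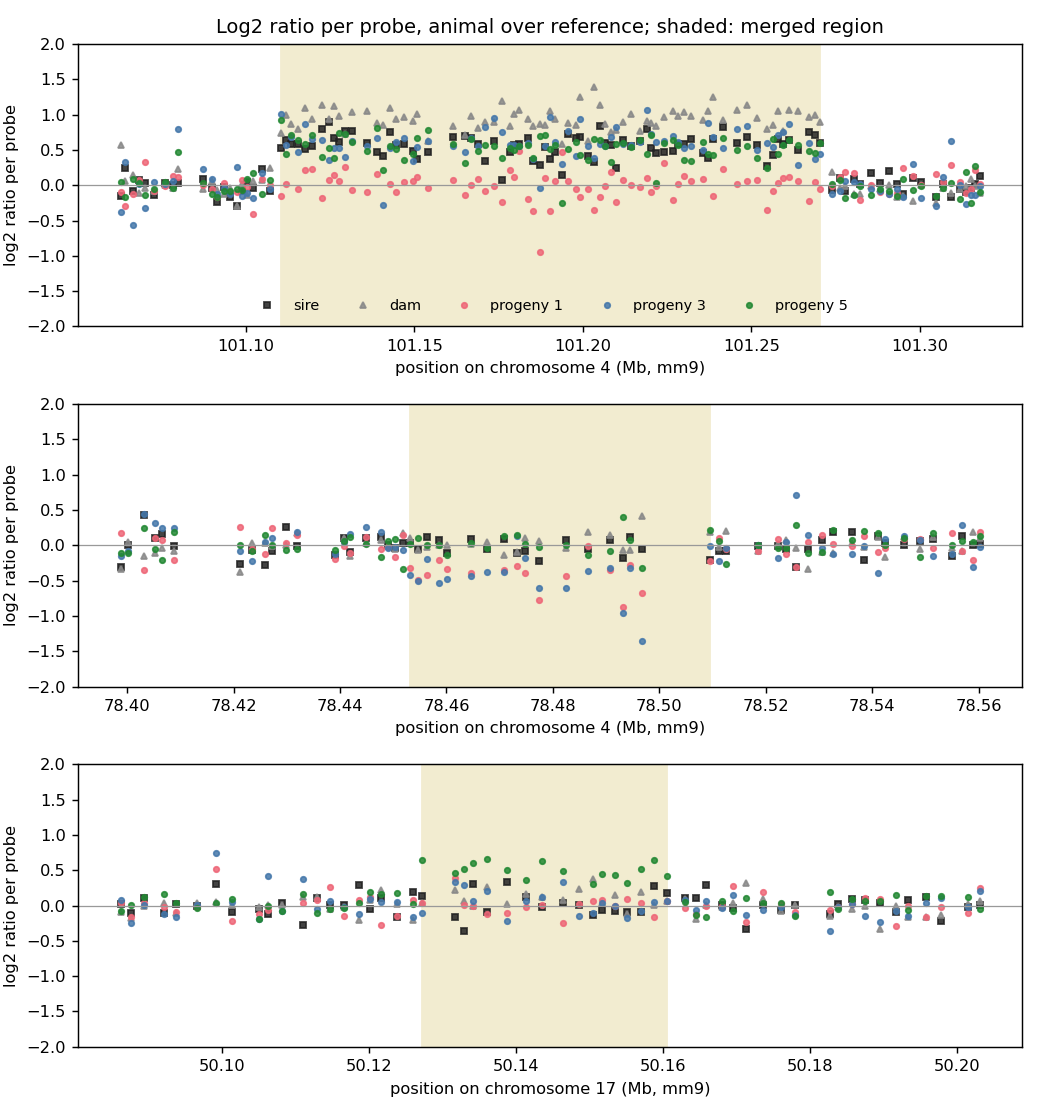
Log2 ratio per probe, animal over reference, along 3 regions (position in Mb, mm9) in the sire, the dam and progeny 1, 3 and 5; shading marks the merged region. Progeny 1 lies near 0 in the chromosome 4 gain carried by both parents, progeny 1 and progeny 3 lie low in the 18-probe chromosome 4 loss, and progeny 5 lies high in the 17-probe chromosome 17 gain.

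The full search gave 857 candidates (336 gains and 521 losses), which differed from each parent by at least 0.25 on both arrays, against 271 on the orientation difference. The largest difference lay in progeny 1 for 318 candidates, in progeny 2 for 38, in progeny 3 for 174, in progeny 4 for 173, in progeny 5 for 66 and in progeny 6 for 88. The naming rule picked the 10 with the largest difference, and progeny 1 had the largest measured difference in all 10, although for the chromosome 2 gain the lower bound was higher in progeny 2. After the chromosome 2 gain these were 9 losses of 3 probes, from -1.63 on chromosome 1 (start 48438854) to -1.19 on chromosome 5 (start 150243088), and including chromosome 8 (start 76272080, -1.59) and chromosome 18 (start 27766625, -1.52). Without the most extreme probe the chromosome 18 loss was -0.07, that on chromosome 7 (start 87813035) was -0.08, and that on chromosome 1 from 48438854 was -1.20. On single arrays all 9 losses were deeper with progeny 1 in Cy3 (-2.90 to -1.99) than in Cy5 (-1.06 to -0.26). The chromosome 1 loss from 48438854 was -2.90 in Cy3 and -0.365 in Cy5. Of these 10, 8 had at least 1 probe in an unevenly scattered area of the progeny 1 array with the animal in Cy3. The stricter search left 12 candidates, against 2 on the orientation difference, and 5 of the 12 had their largest difference in progeny 1. In shuffled noise drawn from all spots, a search from 3 probes left 14 false calls of at least 5 probes and a score of 8 for progeny 1. It left 0 for the sire and for progeny 3. The stricter search started from 5 probes, so these counts may understate its own false calls. Besides the regions on chromosomes 2, 4 and 17, the candidates of the stricter search were 9 regions of 5 or 6 probes, 8 losses and 1 gain. Normexp left 11 candidates, and the count was 540 without progeny 1 and 1289 without the sire.

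At single probes, 32961 reached 0.5 in the same direction on both arrays of an animal, summed over the 8 animals, while 84144 reached it in opposite directions. Progeny 3 (9548) and progeny 4 (7452), which share a scan day, had the most in the same direction and progeny 2 the fewest (1024). The sire had 2172, the dam 1951, progeny 1 had 3832, progeny 5 had 2719 and progeny 6 had 4263. The opposite direction held more probes than the same direction in every animal, from 4636 in progeny 5 to 17273 in progeny 2. A minimum of 0.8 left 5483, and normexp left 459.

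A probe-wise test asked where the progeny as a group differed from the reference male. All 14 probes called lay in regions described above. Within the chromosome 13 gain from 65468928, 10 probes were higher, by 0.50 to 0.88. Within the chromosome 14 loss, 3 were lower, by -0.64 to -0.46. The remaining probe, at 95707465 on chromosome 13, was higher by 1.53 ± 0.08 (SE, adjusted p = 0.00129, limma), with both parents averaging 1.52. All 14 went the same way in 6 of 6 progeny. Of 949333 probes tested, 56473 had an unadjusted p under 0.05, above the share of 0.05 that chance alone would give. The call ended (0 probes, with 31416 at an unadjusted p under 0.05, below that share) when limma's variance was fitted with a trend and robustly. Leaving out single progeny gave 2 probes without progeny 2 or progeny 5, 4 without progeny 6, 6 without progeny 3, 8 without progeny 4 and 12 without progeny 1. Other settings raised the count, to 26 without probes of a dim reference spot, 101 under normexp and 103 with all 16 arrays and a block per animal. The reference is 1 animal whose own spread is not in the test, and a change in that animal would appear in all progeny.

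The same test between the 6 progeny and the 2 parents called 0 probes, so no single probe passed the threshold for a difference between these groups. Regions carried by some progeny alone, such as the chromosome 2 gain, the chromosome 4 loss and the chromosome 17 gain, held no called probe. At an unadjusted p under 0.05 there were 27635 probes. This is fewer than the share of 0.05 of all tested probes that chance alone would give, so the count is no sign of missed differences. In simulated data of this design with 50000 probes, each change was set in all 6 progeny. There limma recovered 25% of changes of 0.5 and 87% of changes of 1 between progeny and parents. With 949333 probes tested and sparser changes these shares may be lower, so smaller differences could have been missed. The shares do not hold for changes in some progeny alone, which widen the spread within the group. The chromosome 2 gain, at 3.27 to 4.39 in progeny 1 to 4, was not called, so large changes of that kind could also be missed. The parents were scanned on 1 day that held no progeny, and with scan day as a random block the count was also 0.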

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

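All tests in this part were chosen after the result was seen, except the share of spots in the densest tiles of the progeny 1 array. Of 14 results compared over the 6 progeny, 5 had 1 animal far from the other progeny by a gap rule (Dixon, critical value 0.625), which chance gives in about 1 in 20 groups. The 5 cannot be set against that rate. The flagged gain on chromosome 17 was called in progeny 5 alone, so its flag follows from how it was picked. The flagged call counts of progeny 1 come from the same arrays.

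Progeny 1 stood apart in its number of interval calls, with 1519, and in its calls on the orientation difference, with 785. Of its 1519 interval calls, 1477 were losses. Copy number losses in the animal are argued against by the ratio of their median on the 2 arrays: the value with the animal in Cy5 was 0.179 times that in Cy3, while the other 7 animals gave 1.03 to 1.34. On the Cy5 array alone progeny 1 had 184 calls, within the 51 to 226 of the other animals, and on the Cy3 array alone 4004, consistent with noise of the Cy3 array. The densest 20 of 400 tiles held 32.2% of the spots in called losses, where over 50% had been predicted, and this share alone decides nothing. Of the called losses 93.3% had at least 1 spot there, against 11.4% to 20.3% of the losses in the other animals, consistent with a stripe that sets a single probe of a call; the tiles were picked on these losses, and 99 losses had no spot there.

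Signal on chromosome 2 from 70079530 in progeny 1 to 4, and not in the parents or the reference, was singled out for its size and not by the gap rule. An artefact of the array or the scan is argued against by the dye swap: on all 8 arrays of these progeny, 4 with the animal in each dye, the 4 spots of the animal channel were well above background (signal 565 to 710) and none of the reference channel (27.4 to 65.3). Copied fragments carried over into the DNA before labelling stay open, since 0 of the 4 scan days held both animals with and animals without the signal and the highest percentile of the region's signal among all spots of its channel was 31.2, which a small amount could give. A parent other than the sire or dam may have brought the sequence: 1 further region of at least 10 probes was carried by 2 or more progeny and neither parent (the loss on chromosome 4 from 78453216), too few to decide. The gain on chromosome 4 from 101110482 bears on the parentage or identity of progeny 1 as well, at 0.56 in the sire, 0.94 ± 0.017 in the dam and -0.007 ± 0.024 in progeny 1, but how each parent's copies are divided between its chromosomes is not known, and a new change in a parent's germ line was not tested.

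The dam, progeny 5 and progeny 6 shared changed regions and the high X and low Y ratios. For an autosomal loss passed on by the dam, at most 1 copy would be missing in the progeny, and 0 of the 11 losses of these 3 animals alone lay below -1 by more than 2 SE in both progeny. The lowest, on chromosome 3 from 25417435, was -1.68 (SE 0.27) in progeny 6 and -1.53 (SE 0.30) in progeny 5 over 3 probes, but -0.73 and -0.83 over 6 probes of the locus, so such a loss is not excluded. On chromosome 6 from 104236953 the SE was near the size of the mean (-1.13, SE 1.07 in progeny 5). Over 5 probes of that locus progeny 5 went from -0.65 to 0.00, and progeny 6 from -0.76 to -0.06, without the most extreme probe. Where 1 probe sets the mean, the rule of 2 SE cannot decide. For probes that share sequence with the X or Y chromosome, the 11 losses against at most 4 in any of the other 29 sets of 1 parent and 2 progeny decide nothing, since that count restates the pattern. Losses on different chromosomes pass to progeny independently of each other. The 11 losses lay on chromosomes 2, 3, 5, 6, 7, 9, 10, 11 and 16, all in the same 2 progeny. With at most 4 losses in any other such set, this argues against separate inheritance from the dam for the 11 as a set. Sets with other numbers of progeny were not counted. Inheritance stays open for any single loss and for the gain on chromosome 8, and shared X or Y sequence stays open for the losses.

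The correlation between the 2 orientations was lowest in progeny 2, at -0.490. The gain on chromosome 4 from 101110482 was at -0.007 in progeny 1. The gain on chromosome 17 from 50127196 was at 0.498 in progeny 5.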

How the results depend on the processing

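Alternatives chosen after the data were seen were the scan day block, the uneven areas left out, the mean without the most extreme probe, and the calls without progeny 1. The causes of the moves below were not tested, apart from effects of construction. Stricter settings and fewer animals leave fewer calls by construction. The normexp offset of 50, added to both channels, pulls ratios toward 0 by construction, and the minimum ratios were left unchanged. Interval calls (2944) were 348 under normexp, 6724 at a score of 5, 998 at a score of 8, 1413 with at least 5 probes, 5099 and 1162 with the animal in Cy3 or Cy5 only, 1210 without dim probes, 1425 without progeny 1, 1645 without uneven areas, 61 with these left out, at least 5 probes and a score of 8, and 1127 without the most extreme probe. Merged regions (2836) were, in the same order, 298, 6321, 966, 1369, 5014, 1074, 1164, 1342 to 2731 without single progeny, 1548 and 32. Regions in progeny and neither parent (2301) were 272, 4956, 875, 1171, 4000, 467, 1115, 836 to 2207, 1038 and 17. Candidates (857) were 11, 1934, 197, 251, 3990, 463, 154, 540 to 1289 without single animals and 12 in the strictest search; without uneven areas alone they were 643, and 2301 with no difference from the parents required. The value table (2982 calls) and a minimum mean of 0.4 (2850 calls) stayed within 1.5 times of all 4 counts.

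Probes past 0.5 on both arrays (32961) were 5483 at 0.8, 11629 without dim probes and 459 under normexp. Probes called by limma against the reference (14) were 0 with trend and robust fitting (31416 at an unadjusted p under 0.05), 26 without dim probes, 103 with all 16 arrays and a block per animal, 101 under normexp and 2 to 12 without single progeny; they were 14 with the scan day block. Against the parents limma called 0 under every alternative, with 23935 to 39319 at an unadjusted p under 0.05. These counts, and the 31416 above, lay below the share of 0.05 of tested probes that chance alone would give. Of 28 splits of the 8 animals into 6 and 2, the real one included, 27 called 0 probes and 1, with progeny 3 and 4 (a shared scan day) set apart, called 14. Under normexp X was 0.62, 0.63 and 0.49 and Y was -0.28, -0.20 and -0.35 in the dam, progeny 5 and progeny 6; the other 58 of 64 X and Y values moved by less than the SD over probes. For regions of at least 10 probes, the alternatives were compared with values that keep the uneven areas, unlike the values reported above. Of these 192 values, 152 moved little and 40 moved. A change of sign occurred in 20, each under 0.05 in size before the change of setting. Low signal over background limits Y ratios and the chromosome 2 region, which the filter on dim probes removes. No paired analysis was possible because each animal has 1 replicate and progeny pair with no single parent. The gene-level alternatives and GC correction could not be run.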

Other observations

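All observations in this part were chosen after the values were seen, and no explanation was tested for them. Of the 12 regions of the full search carried by the dam, progeny 5 and progeny 6 alone, the 11 losses had 3 probes each. In the stricter search, the same 3 animals carried losses of 5 probes on chromosome 3 from 132542035, on chromosome 6 from 104238274 and on chromosome 16 from 40842804, at -0.75, -0.89 and -0.49 in the dam, -0.66, -0.65 and -0.38 in progeny 5, and -0.65, -0.76 and -0.54 in progeny 6. None of these 3 losses kept a mean of 0.25 in size in every calling animal without its most extreme probe.

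The stricter search also gave 16 changes of 5 probes carried by 1 animal alone, in parents as in progeny, with 4 in the sire, 1 in the dam, 5 in progeny 1, 2 in progeny 2, 1 in progeny 4 and 3 in progeny 6. Of these, 8 held in the calling animal without the most extreme probe. The 4 in the sire were losses of -0.50, -0.49 and -0.50 on chromosomes 6, 12 and 13 and a gain of 0.52 on chromosome 10, none of which held, and the dam had a gain of 0.50 on chromosome 1, which held. Among the progeny, losses that held stood at -0.83 on chromosome 5 from 150243088 and -0.54 on chromosome 18 from 17450863 in progeny 1, at -0.59 on chromosome 12 from 58325688 in progeny 2, at -0.66 on chromosome 13 from 73395009 in progeny 4, and at -0.595 on chromosome 2 from 86701969 and -0.57 on chromosome 19 from 41884752 in progeny 6. A gain of 0.53 in progeny 2 on chromosome 18 from 29569115 held as well. The chromosome 5 loss of progeny 1 was uneven between its arrays, at -1.33 with the animal in Cy3 and -0.33 in Cy5. The other loss of progeny 6, on chromosome 6 from 132817646, went from -0.59 to -0.24, and the other 3 losses of progeny 1 did not hold. A gain of 6 probes on chromosome 1 from 30812632 stood at 0.64 ± 0.287 (SE over probes) in progeny 3 and 0.43 ± 0.345 in progeny 6, and without the most extreme probe at 0.405 and 0.09. Of the 12 candidates of that search, 9 held in the calling animals without the most extreme probe.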
